A study of Mus musculus with 7 samples.

How the data were processed

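Gene expression was measured in medullary thymic epithelial cells with high MHC class II, sorted from the thymus of NOD mice that had received bone marrow as pups. The reconRAG1KO group (4 samples) came from RAG1-null mice and is the control named by the series, and the reconSCID group (3 samples) came from mice with the SCID mutation. Both groups and the replicate numbers were taken from the sample titles, which call the samples biological replicates without saying how many thymi each one holds. Per the labels, total RNA (6 µg) was made into biotinylated cRNA by the Affymetrix protocol.

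The deposited values are an intensity per probe set on a linear scale. The authors had already summarised the probes into probe sets and brought the arrays to nearly the same level, and the method of summary and normalization is not given in the sources used here. The table held 34760 probe sets with no missing value and 0 values below 1, so log2 was taken with no pseudocount. No control probe sets were named in the table, so none were removed. Of the probe sets, 21640 had 1 gene symbol in the platform annotation, 1321 had several and 11799 were unnamed in the annotation table used here. Gene IDs of 21553 probe sets with 1 symbol were found in the RefSeq table of assembly GRCm38.p6, which was used for names and gene lengths, and 0 symbols needed an update. No coordinates are printed because no genome build is named for the array values. Median intensities lay between 88.6 and 96.3 per array. The number of arrays limits the precision.

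In 16049 probe sets (46.2%) at least 2 of the 7 arrays held exactly the same deposited value, which can make the spread between arrays look smaller than it was. The cause of these ties was not tested.

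Probe sets were compared between groups with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 34760 probe sets and a threshold of 0.05. Fold changes are reconSCID minus reconRAG1KO on the log2 scale. Gene lists were tested on 1 probe set per gene, the one with the highest mean, over 19937 genes. The test was camera with a preset correlation of 0.01, two-sided and adjusted over 31 lists. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of the list mean over all 35 splits of the samples, whose smallest possible p is 0.02857. The lists, tests, alternative settings and the rule for named genes were fixed before the data were examined.

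The named genes are Aire, Prkdc and Rag1, then up to 12 genes per direction with the largest fold among those past the threshold whose groups do not overlap, and up to 4 members with the smallest unadjusted p in each list described. Where fewer than 12 passed in a direction, the genes with the smallest unadjusted p filled the remainder, without clone or model names and with 1 probe set per gene. A count given as adjusted over the list alone used the members' p-values only.

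The arrays fell into 2 sets by their correlations. ReconRAG1KO replicate 4 and reconSCID replicate 2 correlated at 0.972 with each other and at 0.922 to 0.947 with the other 5 arrays, which correlated at 0.976 to 0.990 among themselves. Labels name no batch. Each set held both groups, so the value of each list called is given also with the array set as a block and within each set, a choice made after seeing the data. The set of 2 arrays has 1 array per group and allows no test of its own. Within the sets 20 splits of the samples are possible, and the smallest permutation p is 0.05.

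The test was tried on simulated data for reconSCID against reconRAG1KO over 34760 probe sets, with 100 genes changed 2-fold and 100 changed 4-fold. With no difference between array sets, 89 and 99 of them were called, with 12 unchanged probe sets. With the observed difference between array sets, the fit without a block called 37 and 90, with 0 unchanged ones, and the fit with the block called 84 and 99, with 9 unchanged ones. The simulated shift of -0.30 in the Aire-induced list was called in each of the 3 simulations, with medians of -0.35, -0.27 and -0.33. In them 0 other lists were called. Simulated genes varied independently, whereas the correlation estimated from the real arrays was 0.135 for Aire-induced antigens and 0.432 for B cell genes. The simulations therefore cannot check list calls among genes that vary together.

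Alternative settings fixed beforehand were quantile normalization, centring on the array median, a filter on low values, a pseudocount of 16, a robust fit with an intensity trend, array weights, the replicate number as a block, leaving out each sample in turn, a fold threshold of 2, an unadjusted threshold, other set tests and the mean of all probe sets of a gene. Alternatives added after seeing the data were the array set as a block, the 5 arrays of the larger set alone, probe sets with 1 symbol, probe sets whose 7 values all differ, the Aire-induced list without S100a8, and leaving out each sample in turn with the block. A covariate for RNA quality from control probe sets was planned and not run. Lists of general epithelial genes (17), of immunoglobulin genes (11) and of the keratin, claudin, Epcam and Cdh1 members of the medullary list (10) were written after values had been seen. The first of these was drawn up from general knowledge of epithelial markers before most of its members had been looked at, and a further marker considered for it, of which no value was seen, is not reported here. Of the 22 measured Aire-induced antigens 18 also stand on another fixed list, mostly that of the tissue they belong to, and of the 17 general epithelial genes 8 do.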

Results

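The arrays measured transcripts of medullary epithelial cells, the thymic stromal cells that display antigens of other tissues to developing T cells. Cells with high MHC class II were sorted 6 to 8 weeks after pups of 2 to 4 days had been given bone marrow, 6 h after irradiation with 200 rad. The marrow supplied the thymocytes that both mutant strains lack and on which the medulla depends. There were 4 reconRAG1KO samples, from mice without the recombinase RAG1, and 3 reconSCID samples, from mice with the mutation in Prkdc, the gene of the catalytic subunit of DNA-dependent protein kinase (DNA-PK). RAG1 acts in lymphocytes, whereas DNA-PK is active in most cells and binds Aire, the transcriptional regulator through which these cells express tissue-restricted antigens. The comparison asks how expression in the medullary epithelium differs where DNA-PK is defective. All recipients were irradiated and given marrow. The design therefore cannot separate a direct effect on expression from a response to irradiation or transfer that differs between the groups.

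Of the 3 genes the design is about, Aire was lower in reconSCID by an interval that excluded 0 with the array set as a block and included 0 without it. Aire (probe set 10370397) had a mean log2 intensity of 11.20 ± 0.49 (SD, n = 4) in reconRAG1KO and 10.63 ± 0.87 (SD, n = 3) in reconSCID. The log2 difference of Aire was -0.57, with a 95% interval from -1.63 to 0.49. With the array set as a block the difference of Aire was -0.67, with an interval from -1.25 to -0.09, its unadjusted limma p was 0.03117 and its adjusted p 0.3589. Without reconSCID replicate 3 the blocked difference was -0.34, with an interval from -0.60 to -0.09, and the interval excluded 0 also without reconSCID replicate 1 and included it without each of the other 5 samples. Without the block the difference was -0.12 without reconSCID replicate 3, -0.99 without reconSCID replicate 2 and -0.33 without reconRAG1KO replicate 4. General epithelial genes, a list written after values had been seen, had a blocked median of -0.50, with 17 of 17 lower. Their blocked differences ran from -0.80 (Krt18) to -0.18 (Lsr), a range that holds the value of Aire. Their median was -0.06 within the set of 2 arrays. Fezf2, of the medullary list, had a blocked difference of -0.57, with an interval from -1.07 to -0.07. Whether Aire fell by more than the general epithelial genes was not tested. In samples high in Xist, reconRAG1KO replicate 2 and reconSCID replicates 3 and 1, Aire measured 10.895, 9.725 and 10.702. It measured 10.898 to 11.928 in the others. Sex was in no fit. Prkdc (probe set 10433797) measured 7.26 ± 0.07 (SD, n = 4) and 7.40 ± 0.23 (SD, n = 3), a difference of 0.14 with an interval from -0.16 to 0.44. Without reconSCID replicate 3 the difference of Prkdc was 0.007, or 0.029 with the block. The SCID mutation changes a base of the coding sequence, so a transcript level does not check that label. Rag1 (probe set 10485372) measured 8.22 ± 0.84 (SD, n = 4) and 8.26 ± 1.18 (SD, n = 3). Transcripts of Rag1 can also come from developing lymphocytes of the transferred marrow, so this level does not check the genotype of the recipient.

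The arrays did not form 1 homogeneous set. ReconRAG1KO replicate 4 and reconSCID replicate 2 stood apart from the other 5 arrays, and 13914 probe sets differed between these sets after adjustment, of which 5611 were lower and 8303 higher in the 2 arrays. Ribosomal protein genes were lower in the 2 arrays in 58 of 60 cases, with a median log2 difference of -1.30. Among single genes, Rpl9 averaged 13.05 in the 5 arrays and 8.12 in the 2 arrays, and the respiratory chain gene Cox6a1 averaged 11.56 and 7.87. Each set held samples of both groups.

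**Figure D1:**
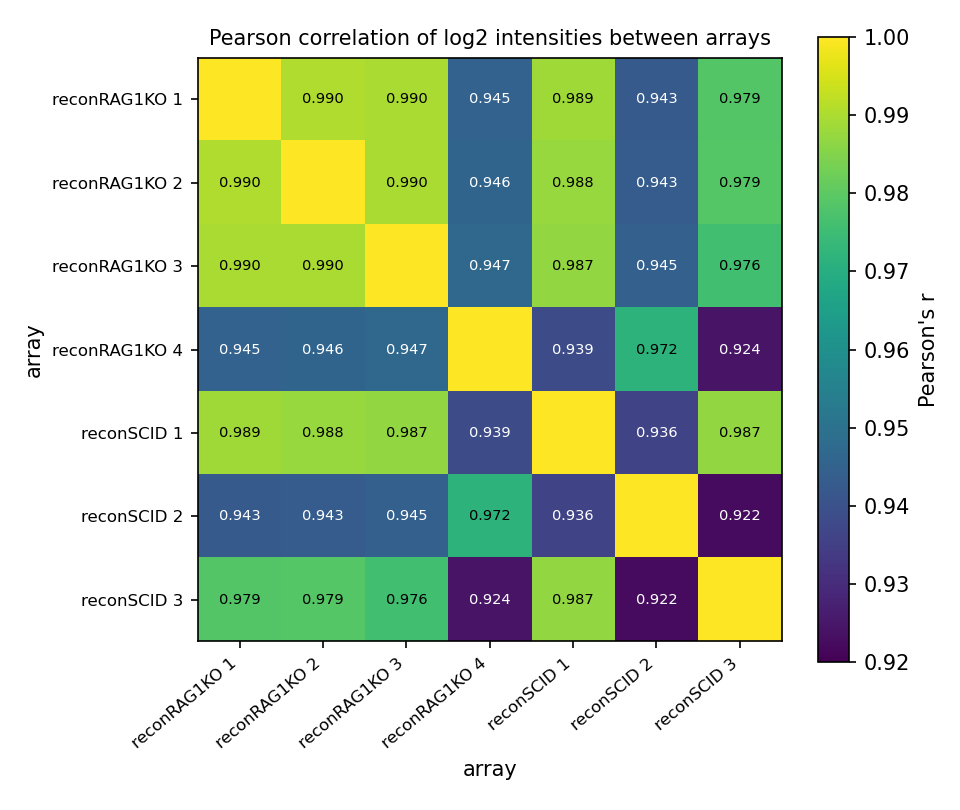
Pearson correlations of log2 intensities over 34760 probe sets for each pair of the 7 arrays, named by group and replicate on both axes. ReconRAG1KO replicate 4 and reconSCID replicate 2 correlate at 0.972 with each other and at no more than 0.947 with the other arrays.

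No single probe set passed in the comparison of reconSCID with reconRAG1KO. By limma, 0 probe sets were higher and 0 lower at an adjusted p under 0.05, while 765 were higher and 394 lower at an unadjusted p under 0.05, or 3.33% of 34760. With array weights in the fit, 47 passed as higher and 10 as lower. The weights of reconSCID replicates 1, 2 and 3 were 4.79, 0.12 and 0.80, so the reconSCID mean of that fit rests mostly on replicate 1. With the array set as a block 0 and 0 passed, while 2271 were higher and 2005 lower at an unadjusted p under 0.05, or 12.3%. In the 5 arrays of the larger set alone 0 and 0 passed, and 3082 and 2306, or 15.5%, had an unadjusted p under 0.05. Of the probe sets with an unadjusted p under 0.05 in the fit without the block, 552 higher and 119 lower were unnamed in the annotation table, and 201 higher and 255 lower had 1 gene symbol.

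None of the genes with the smallest unadjusted p passed. Among those lower in reconSCID, Mep1a, the intestinal protease meprin alpha, measured 7.75 ± 0.24 (SD, n = 4) in reconRAG1KO and 6.66 ± 0.23 (SD, n = 3) in reconSCID, a log2 difference of -1.08 ± 0.17 (SE). Cldn13 had a difference of -1.01, the gastric protease precursor Pgc -0.88, Mucl2 -0.94, Aoc1 -0.78, the cornified envelope gene Sprr2d -0.68, Cytl1 -0.67, the steroid-synthesis enzyme Cyp11a1 -0.61 and Cyp1a2 -0.53. Zfand1, Rps4l and B9d1 completed the 12, at -1.07, -0.74 and -0.55. On the higher side, the immunoglobulin kappa segment Igkv5-43 had the largest difference, 2.86 ± 0.69 (SE), and near-identical segments make its probe set uncertain. Fcmr, the IgM Fc receptor of B cells, followed at 1.31 and Muc15 at 0.95. The other 9 lay between 0.34 and 0.58 and were Jmjd1c (0.49), Angptl7 (0.58), Slk (0.43), Lin54 (0.43), Ppp3ca (0.37), Gpr82 (0.34), Olfr114 (0.50), the semaphorin receptor Nrp1 (0.47) and the DNA polymerase gene Pola1 (0.46).

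Antigens known to depend on Aire fell as a group in reconSCID. Their median log2 difference was -0.27 over 22 measured genes, 20 of which were lower, with a camera adjusted p of 1.156e-09 at the preset correlation and an adjusted p of 0.2333 with an estimated correlation. Every reconSCID sample had a lower list mean than every reconRAG1KO sample, and the exact permutation p was 0.02857, the smallest that the 35 splits can give, or 0.2952 after adjustment over the lists. Within the array sets the permutation p was 0.05, the smallest that 20 splits can give. Many lists reached this 0.05, among them brain and eye, endothelial and sex-linked genes, which were not called. It was not adjusted over the lists. Adjusted over the list alone, 3 members passed, or 7 with the array set as a block, and over all probe sets 0 did in either fit. The 3 were the secreted gland protein gene Mucl2 (-0.94 ± 0.21, SE), the liver enzyme gene Cyp1a2 (-0.53 ± 0.12, SE) and the retinoic acid binding protein gene Crabp1 (-0.65 ± 0.15, SE). The milk protein gene Csn2 differed by -0.61 and passed over the list alone only with the block. The list median was -0.29 with the array set as a block, -0.29 within the 5 arrays and -0.26 within the 2 arrays, and -0.15 without reconSCID replicate 3. It was -0.43 over the 9 members above the median level of all probe sets, and -0.53 over the 13 members whose 7 deposited values all differed. General epithelial genes, written down after values had been seen, had a median of -0.50 with the block, -0.72 within the 5 arrays and -0.06 within the 2 arrays. With the block 17 of 17 were lower, at a camera p of 2.068e-08 and a p of 0.178 with an estimated correlation, and the exact permutation p of their mean was 0.4 over all splits and 0.05 within the array sets. Without reconSCID replicate 3 their blocked median was -0.25.

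**Figure D2:**
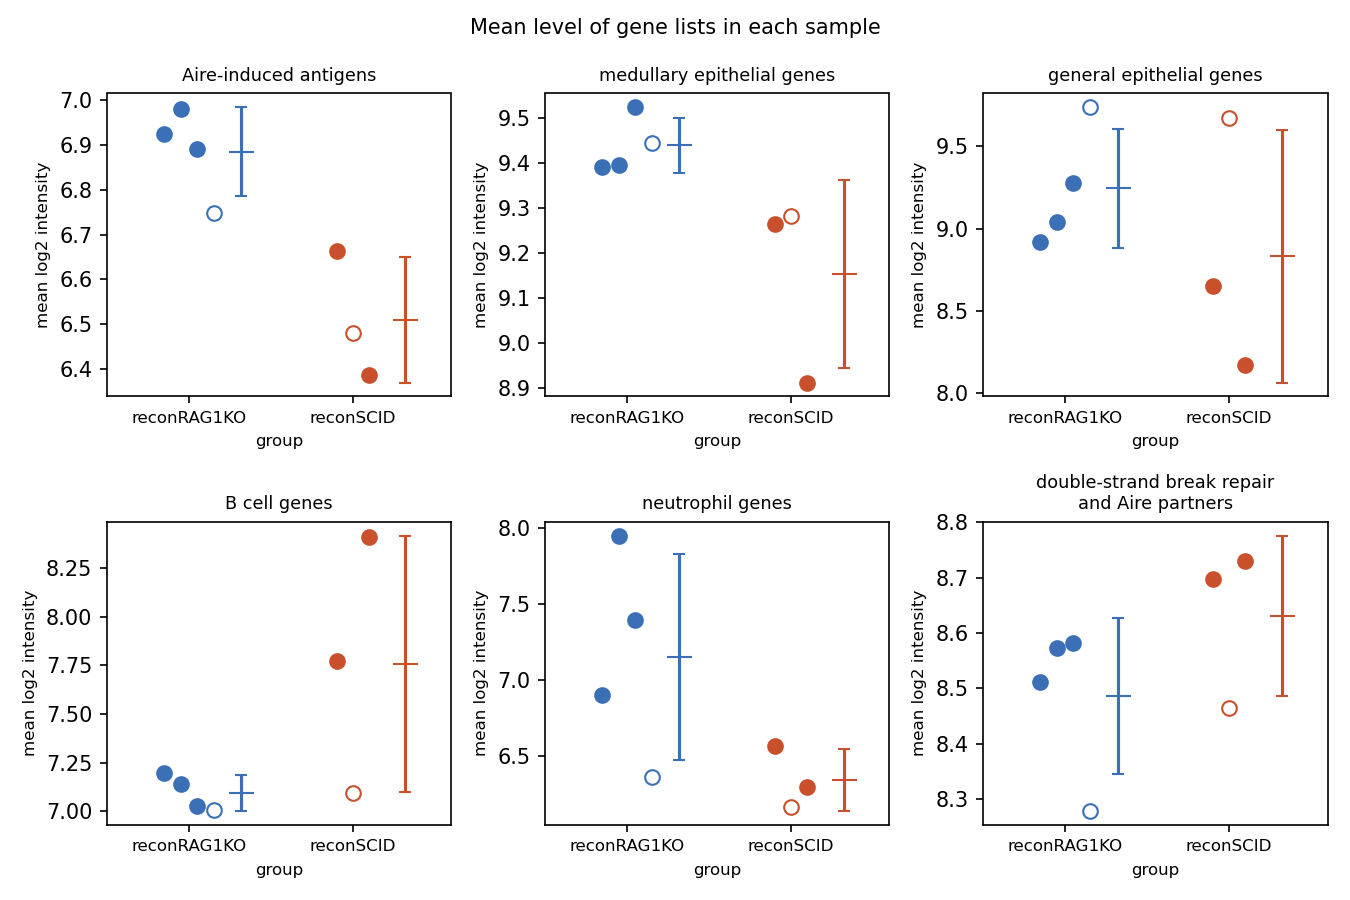
Mean log2 intensity of 6 gene lists in each sample by group, as points, with bars for the group mean ± SD (n = 4 and n = 3) and open points for the 2 arrays of the smaller set. The 3 reconSCID samples lie below the 4 reconRAG1KO samples for the Aire-induced antigens.

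Antigens known not to need Aire did not pass as a group. Their median was -0.05 over 7 genes, with a camera adjusted p of 0.4964, and it was -0.04 with the array set as a block, -0.02 within the 5 arrays and -0.21 within the 2 arrays. Whether the Aire-induced and Aire-independent lists differed from each other was not tested. Glutamate decarboxylase genes Gad1 and Gad2 had differences of -0.08 and 0.09, the thyrotropin receptor gene Tshr -0.15 and the fatty acid binding protein gene Fabp1 -0.05. In reconRAG1KO, Gad2, Tshr and Fabp1 averaged 4.74, 4.69 and 5.71, below the array medians of 6.47 to 6.59, and Gad1 averaged 7.14. A fall would be hard to see in members at such low levels.

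Genes of the medullary epithelium itself also fell. The median was -0.25 over 42 genes, 37 of them lower, with a camera adjusted p of 1.604e-07 and an adjusted p of 0.3238 with an estimated correlation. The exact permutation p of the list mean was 0.02857, or 0.2952 after adjustment over the lists, and 0.05 within the array sets. Adjusted over the list alone 0 members passed, and with the array set as a block 1 higher and 4 lower did. Histidine decarboxylase Hdc differed by -0.82 ± 0.27 (SE), the tight junction gene Cldn4 by -0.71 ± 0.24 (SE), the chemokine gene Ccl20 by -0.52 ± 0.21 (SE) and the NF-kappaB subunit gene Relb by -0.33 ± 0.14 (SE). The list median was -0.28 with the array set as a block, -0.35 within the 5 arrays and -0.17 within the 2 arrays. Without reconSCID replicate 3 it was -0.14 and without reconSCID replicate 2 it was -0.48. With the array set as a block, general epithelial genes had a median of -0.50, the 10 keratin, claudin, Epcam and Cdh1 members of this list -0.56 and B cell genes 0.59. Within the 2 arrays these medians were -0.06, -0.21 and 0.09. MHC class II genes, by which the cells were sorted, had a median of -0.01 over 13 genes and a camera adjusted p of 0.8375. They were called higher within the 5 arrays (median 0.09) and without reconSCID replicate 2 (0.22), and had a median of -0.19 within the 2 arrays. The invariant chain gene Cd74 measured 13.39 and 13.35.

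Tissue-restricted genes fell in several tissue lists and were not called in others. Keratinocyte differentiation genes had a median of -0.30 with 35 of 42 lower (camera adjusted p = 2.72e-13, adjusted p = 0.3089 with an estimated correlation), and Sprr2d was the 1 member that passed adjusted over the list alone without the block. Krtdap and Sbsn, both of the cornifying epidermis, differed by -0.77 and -0.41, and Sprr1a by -0.64. Stomach and intestine genes had a median of -0.16 with 35 of 42 lower (camera adjusted p = 1.058e-08, adjusted p = 0.2333 with an estimated correlation), led by Pgc, the antimicrobial lectin gene Reg3g (-1.09), Lypd8 (-0.61) and the apolipoprotein gene Apoa4 (-0.57). Pancreas genes had a median of -0.11 with 25 of 34 lower (camera adjusted p = 6.428e-06, adjusted p = 0.4933 with an estimated correlation), and the hormone genes Gcg and Sst differed by -0.55 and -0.51. With the array set as a block the medians of these 3 lists were -0.32, -0.17 and -0.12, and 5, 6 and 1 members passed as lower adjusted over the list alone. The exact permutation p of their means was 0.08571, 0.02857 and 0.2, and 0.05 for each within the array sets. They were -0.34, -0.21 and -0.12 within the 5 arrays and -0.19, -0.04 and -0.12 within the 2 arrays, and without reconSCID replicate 3 they were -0.11, -0.10 and -0.05. Without reconRAG1KO replicate 4 the pancreas median was -0.03, and without reconSCID replicate 2 it was -0.20. General epithelial genes had a median of -0.50 beside these lists, with the array set as a block, and of -0.06 within the 2 arrays.

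Liver, lung and airway, salivary and lacrimal, muscle and cortical epithelial genes were called lower with medians of -0.09, -0.10, -0.06, -0.06 and -0.18. Their adjusted p with an estimated correlation was 0.4933, 0.6802, 0.6802, 0.7669 and 0.5904, and each lost the call without at least 1 of the samples. The exact permutation p of their means was 0.2286, 0.3143, 0.2286, 0.4286 and 0.5143, and within the array sets 0.05, 0.05, 0.05, 0.15 and 0.05. With the array set as a block their medians were -0.10, -0.13, -0.08, -0.08 and -0.29, and the salivary list was no longer called, at an adjusted p of 0.09633. Adjusted over the list alone 0 members of these lists passed, and with the block 1, 1, 0, 0 and 5 did as lower. Within the 5 arrays they were -0.12, -0.11, -0.11, -0.08 and -0.33, and within the 2 arrays -0.02, -0.11, 0.00, 0.03 and -0.26. Single samples moved these medians by over 1.5 times. Without reconRAG1KO replicate 4 they were -0.03, -0.01, -0.01, -0.03 and -0.18, without reconSCID replicate 1 -0.04, -0.10, -0.02, -0.08 and -0.22, without reconSCID replicate 2 -0.17, -0.22, -0.17, -0.13 and -0.46, and without reconSCID replicate 3 -0.04, -0.06, 0.02, 0.00 and -0.12. The cortical median was -0.29 without reconRAG1KO replicate 1 and -0.28 without replicate 2, the salivary median -0.09 without replicate 3, and the muscle list lost its call without replicate 1 at -0.05. Among cortical genes the thymocyte attractant Ccl25 differed by -1.37 ± 0.61 (SE), or by -0.84 without reconRAG1KO replicate 4. Beside the lists called lower here, general epithelial genes had a median of -0.50 and B cell genes of 0.59, with the array set as a block. Within the 2 arrays these medians were -0.06 and 0.09. Germ line genes (median 0.00, camera adjusted p = 0.8871, direction higher) and brain and eye genes (median -0.05, camera adjusted p = 0.1014) were not called, although the germ cell lipid binding protein gene Fabp9, which is also on the Aire-induced list, differed by -1.05.

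**Figure D3:**
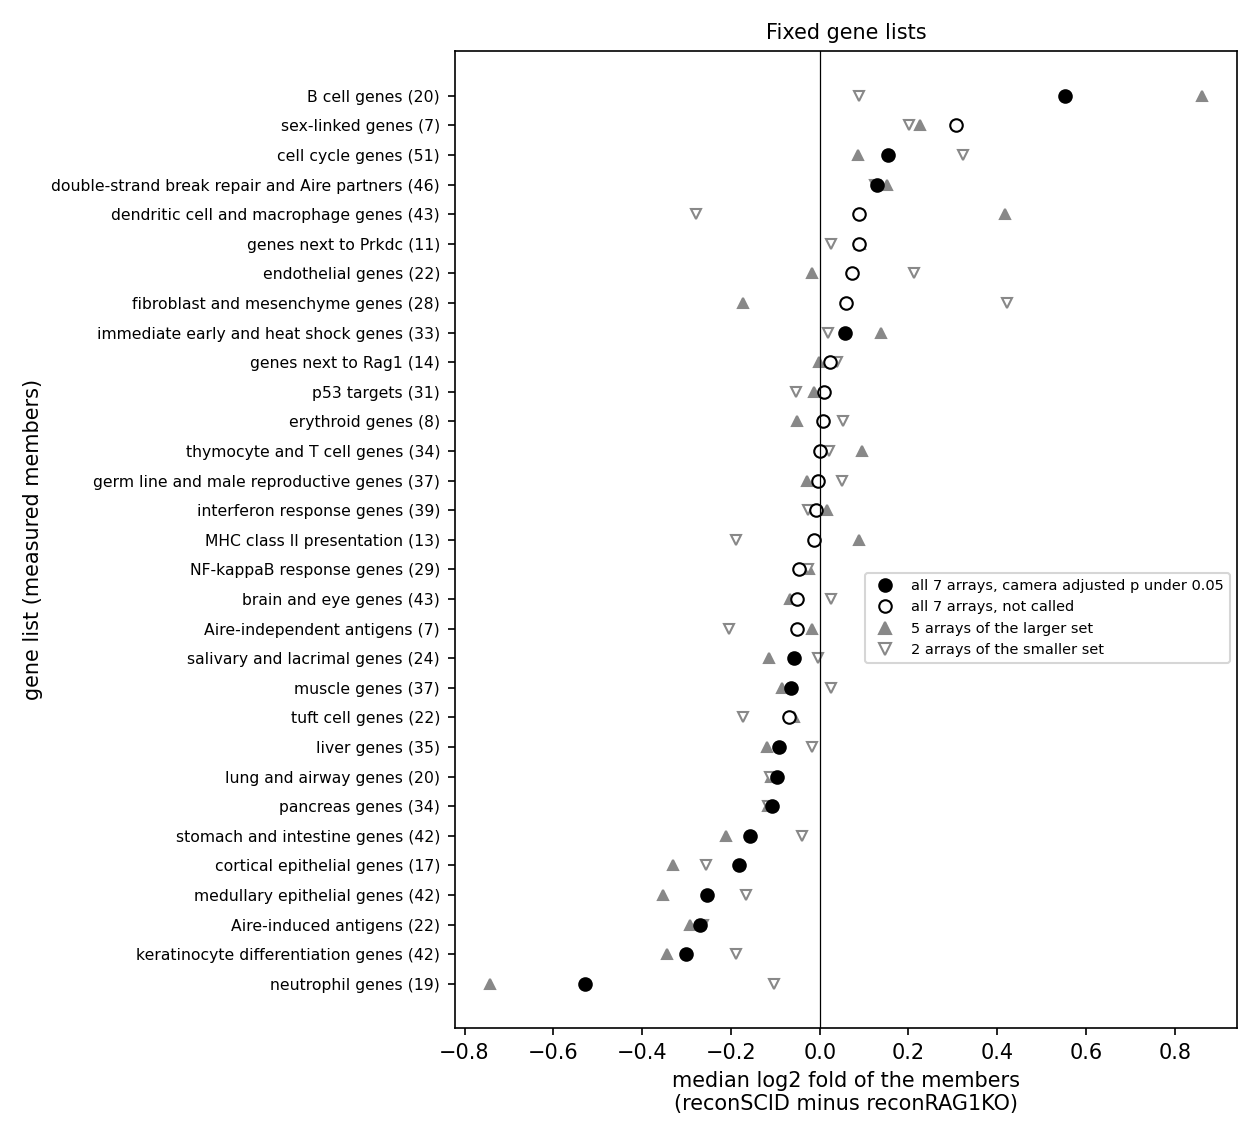
Median log2 difference of the members of each of the 31 fixed lists, reconSCID minus reconRAG1KO, on the horizontal axis, with circles for all 7 arrays (filled where called) and triangles for the 5 and the 2 arrays of the sets. B cell genes have the highest median (0.55) and neutrophil genes the lowest (-0.53).

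Genes of B cells rose in reconSCID. The median was 0.55 over 20 genes, 19 of them higher, with a camera adjusted p of 2.72e-13, an adjusted p of 0.3089 with an estimated correlation and an exact permutation p of 0.08571, or 0.05 within the array sets. The B cell transcription factor gene Ebf1 differed by 0.91 ± 0.32 (SE), Fcrl1 by 0.99 ± 0.34 (SE), the IgM heavy chain gene Ighm by 0.81 ± 0.30 (SE) and the signalling adaptor gene Bank1 by 1.31 ± 0.51 (SE). None of the 20 passed adjusted over the list alone, with or without the block. The median was 0.59 with the array set as a block, 0.86 within the 5 arrays and 0.09 within the 2 arrays. Without reconSCID replicate 3 it was 0.34 and without reconSCID replicate 2 it was 0.85.

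Genes of neutrophils fell, with a median of -0.53 over 19 genes, 16 of them lower (camera adjusted p = 4.926e-08, adjusted p = 0.3238 with an estimated correlation). The exact permutation p of the list mean was 0.1143, or 0.1 within the array sets, and the groups overlapped, with list means of 6.90, 7.95, 7.39 and 6.37 in reconRAG1KO and 6.57, 6.17 and 6.30 in reconSCID. Without reconRAG1KO replicate 2, the highest sample, the median was -0.36. Lcn2 differed by -1.52 ± 0.54 (SE), Ly6g by -1.47 ± 0.61 (SE), Retnlg by -1.39 ± 0.62 (SE) and Stfa3 by -0.53 ± 0.20 (SE). The median was -0.51 with the array set as a block, -0.74 within the 5 arrays and -0.10 within the 2 arrays. S100a8 stood on both this list and the Aire-induced list, and without it the Aire-induced median was -0.24. Dendritic cell and macrophage genes missed the threshold (median 0.09, camera adjusted p = 0.05081) and were called higher with the array set as a block (median 0.19, camera adjusted p = 0.0001511, adjusted p = 0.5601 with an estimated correlation), with medians of 0.42 within the 5 arrays and -0.28 within the 2 arrays. T cell genes (median 0.00), tuft cell genes (-0.07), fibroblast genes (0.06), endothelial genes (0.07) and erythroid genes (0.01) were not called, with camera adjusted p of 0.3086, 0.2496, 0.6373, 0.1868 and 0.6477. Without each sample in turn these lists were called in 4, 0, 2, 3 and 0 of 7 fits. The endothelial median then ran from -0.139 to 0.221.

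Genes of double-strand break repair and known Aire partners rose by a small amount. The median was 0.13 over 46 genes, 36 of them higher (camera adjusted p = 8.204e-07, adjusted p = 0.4859 with an estimated correlation, exact permutation p = 0.2571, or 0.05 within the array sets), and it was 0.14 with the array set as a block, 0.15 within the 5 arrays and 0.13 within the 2 arrays. The damage kinase gene Atm differed by 0.44 ± 0.15 (SE), the nuclear pore gene Ranbp2 by 0.44 ± 0.16 (SE), the cohesin gene Stag2 by 0.47 ± 0.17 (SE) and the topoisomerase gene Top2b by 0.54 ± 0.23 (SE). Adjusted over the list alone 0 passed, and 8 did with the array set as a block. Without reconRAG1KO replicate 4 the median was 0.06, and over the 25 members whose 7 values all differed it was 0.19. Cell cycle genes rose by a median of 0.15, with 42 of 51 higher (camera adjusted p = 5.606e-08, adjusted p = 0.5345 with an estimated correlation, exact permutation p = 0.4571, or 0.1 within the array sets), and the call was lost without reconRAG1KO replicate 4, at a median of 0.04. Their median was 0.16 with the array set as a block, 0.09 within the 5 arrays and 0.32 within the 2 arrays. Mcm4, a replication helicase gene that neighbours Prkdc, differed by 0.39 ± 0.12 (SE), Mcm6 by 0.30, Cenpf by 0.31 and Mki67 by 0.34. Beside both lists, with the array set as a block, B cell genes had a median of 0.59 and general epithelial genes of -0.50. Within the 2 arrays these medians were 0.09 and -0.06. Which cells carried the rises in break repair and cell cycle genes was not tested.

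Stress lists moved little. Immediate early and heat shock genes were called higher with a median of 0.06 (camera adjusted p = 0.04043, adjusted p = 0.4933 with an estimated correlation, exact permutation p = 0.3143, or 0.1 within the array sets), led by the heat shock gene Hsph1 at 0.58, and lost the call without each of 4 samples, reconRAG1KO replicates 1 and 4 (medians 0.05 and 0.08) and reconSCID replicates 1 and 3 (0.09 and 0.05). Without reconSCID replicate 2 the median was 0.13. Their median was 0.07 with the array set as a block, 0.14 within the 5 arrays and 0.02 within the 2 arrays. Targets of p53 (median 0.01), interferon response genes (-0.01), NF-kappaB response genes (-0.05) and the genes next to Prkdc (0.09) and Rag1 (0.02) were not called, with camera adjusted p of 0.8375, 0.9157, 0.2496, 0.2496 and 0.6919. Without each sample in turn the NF-kappaB median ran from -0.115 to 0.043, and the list was called in 2 of these 7 fits. Sex-linked genes had a median of 0.31 and a camera adjusted p of 0.05104. Their median ran from 0.092 to 0.486 without each sample in turn, with a call in 3 of the 7 fits. The list pools Xist with Y-linked genes, which differ with sex in opposite directions. ReconRAG1KO replicate 2 had the highest Xist (9.96) and the lowest Uty (6.17). The list median therefore does not measure the mix of sexes.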

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

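The tests in this part were chosen after the results they bear on had been seen, except for the 3 counts of probe sets and lists over the splits of the samples.

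ReconRAG1KO replicate 4 lay far from the other 3 samples of its group, by its gap to the nearest of them as a share of the group's range, in each of the 10 values that stood out among 60 tested. Chance flags about 1 in 20. Its median intensity was 96.3 against 88.6 to 88.7 (share 0.98) and the SD of its log2 values was 1.85 against 2.01 to 2.02 (0.963). Its mean level was higher for liver genes (0.856), pancreas genes (0.953), brain and eye genes (0.88), cortical epithelial genes (0.898) and endothelial genes (0.987). It was lower for interferon response genes (0.92), NF-kappaB response genes (0.975) and Sprr2d (0.88). This array is 1 of the 2 arrays that form the smaller set.

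Other splits of the 7 samples were compared with the real one. The real split gave 0 probe sets past an adjusted p of 0.05, a count that all 35 splits must reach, and the highest of the others also gave 0, so this count decides nothing. For an unadjusted p under 0.05, 10 of the 35 splits gave as many probe sets as the real 1159, and the highest other gave 8108. That split put both arrays of the smaller set into the group of 3, so the high count points to the structure of the arrays. The 9 other splits with as many put 0 or 2 arrays of the smaller set into the group of 3. Among the 20 splits with 1 such array in each group, as in the real split, the real count was the highest and the next was 953, and a share of 1 in 20 is the smallest they can give. For the number of lists called, 10 of the 35 splits gave as many as the real 15, and the highest other called 21, and 4 of the 20 splits did, with 17 as the highest other. Chance is therefore not excluded for the number of lists called. For the Aire-induced antigens, 1 of the 35 splits, the real one, gave a camera p as small as 1.119e-10, and the smallest of the others was 1.582e-07. It was also 1 of the 20 splits with 1 array of the smaller set in each group, the smallest share they can give, and the permutation p of the list mean was 0.2952 after adjustment over the lists, so chance stays open.

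The lower level of Aire-induced antigens in reconSCID stayed below 0 within both array sets, with a blocked median of -0.286, which argues against the array sets as its whole source. RNA of B cells and other blood cells in place of epithelial RNA may account for it: the blocked median of general epithelial genes was -0.498, at least as low as that of the antigens, and the blocked difference between the 2 list means was 0.126 ± 0.165 (SE). The 10 keratin, claudin, Epcam and Cdh1 members of the medullary list gave -0.56. That list was fixed before the data were examined, but these members were picked from it after values had been seen. Most of them also stand on the general epithelial list, so they largely restate its value. In the 2 arrays the general epithelial median was only -0.06 beside -0.26 for the antigens, which rests on 1 sample per group. With the level of Aire as a covariate, the blocked difference in list mean was -0.19 ± 0.07 (SE) against -0.37 ± 0.09 without it, so a lower Aire level cannot be told apart from the group with 3 residual degrees of freedom. With the mean of general epithelial genes as the covariate the blocked difference was -0.23 ± 0.11 (SE), also with 3 residual degrees of freedom. This value cannot tell whether a difference remains beyond the share of epithelial RNA. An effect of the SCID mutation itself, also through the response to irradiation, stays open and untested. Sex was in no fit. Xist was high in reconRAG1KO replicate 2 and in reconSCID replicates 1 and 3, so a part of sex also stays open.

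For the B cell genes, the median within the 5 arrays was 0.861 and within the 2 arrays 0.09, which argues against the array sets as the whole source. A lower share of epithelial RNA alone would raise other cell types alike. The blocked neutrophil median lay below the B cell median by a difference of -1.097, with a spread of 0.238. Blocked medians were 0.19 for dendritic cell and macrophage, 0.06 for T cell, 0.05 for endothelial, -0.02 for fibroblast and -0.01 for erythroid genes. Neutrophil genes were picked for this after values had been seen, and the exact permutation p of their mean was 0.1143. The comparison therefore cannot exclude a lower epithelial share. B cells in the sorted fraction may be the source, which stays open, since the 95% of genes higher with the block and the blocked median of 0.493 in the more abundant 10 restate the pattern and do not test it. B cells carry MHC class II, so a gate on it alone would not remove them, and Cd79a reached 10.40 in reconSCID replicate 3. The B cell list means were 7.78, 7.09 and 8.41 in reconSCID replicates 1, 2 and 3. They were 7.01 to 7.20 in reconRAG1KO, so reconSCID replicate 2 lay within that range. Whether the SCID mutation or sex bore on how many B cells entered the gate was not tested.

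For double-strand break repair and Aire partner genes, the blocked median of 0.145 stayed above 0 within both sets, and it lay at percentile 100 of 10000 random lists matched on level and gene length, whose central 95% ran from -0.04 to 0.07. Both values argue against array sets and against abundance and genomic length as the whole source. Transcript length was not matched. Random genes do not vary together as the members do (estimated correlation 0.235), so the percentile does not measure chance. Cell cycle and B cell genes also lay at percentile 100 and Aire-induced antigens at 0. The call does not hold with an estimated correlation. A different share of dividing cells and an effect of the SCID mutation may each play a part and stay open, and neither was tested. With the block, B cell genes had a median of 0.585 and general epithelial genes of -0.498, and within the 2 arrays of 0.089 and -0.062. Whether that shift between cell types bears on this list was not tested either.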

How the results depend on the processing

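The array set as a block, the 5 arrays of the larger set, probe sets with 1 symbol, probe sets whose values all differ, the Aire-induced list without S100a8 and leaving out each sample with the block were chosen after seeing the data. Counts of probe sets past an adjusted p of 0.05 were 0 and 0 under every alternative except array weights (47 higher and 10 lower). That fit gave the 2 arrays of the smaller set weights of 0.16 and 0.12, and reconSCID replicates 1 and 3 weights of 4.79 and 0.80. With an unadjusted p and a fold of at least 2 the counts were 107 and 23. Without each sample in turn they were 0 and 0. The cause was not tested.

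Aire-induced antigens kept their direction under all alternatives, and so did medullary epithelial genes. The calls were lost with an estimated correlation (medians -0.269 and -0.254, adjusted p 0.2333 and 0.3238) and with fry (adjusted p 0.2422 and 0.3669), and with the array set as a block together with an estimated correlation (medians -0.286 and -0.28, adjusted p 0.3663 and 0.4215) or fry (adjusted p 0.07098 and 0.1466). Without each sample in turn the medians ran from -0.322 to -0.152 and from -0.483 to -0.143. Of the other 29 lists, 13 were called, 0 with an estimated correlation, 0 with fry, 0 with the block and an estimated correlation, and 3 with the block and fry (break repair and Aire partner genes, pancreas genes, and lung and airway genes). The robust fit and the restriction to probe sets with 1 symbol do not enter the list tests and could not move them. Without each sample in turn 9 to 18 were called.

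Direction turned, with a call in the alternative, for MHC class II genes in the 5 arrays (0.089) and without reconSCID replicate 2 (0.223, range without each sample -0.106 to 0.223), T cell genes without reconSCID replicate 3 (-0.099, range -0.099 to 0.216), dendritic cell and macrophage genes without reconSCID replicate 3 (-0.222, range -0.222 to 0.548), and fibroblast genes in the 5 arrays (-0.173) and without reconSCID replicate 2 (-0.301, range -0.301 to 0.300). The cause was not tested. In 55 further list values and 25 gene values a sign changed where nothing was called. The replicate numbers were not taken to pair the samples: deviations of the samples numbered 1, 2 and 3 correlated at 0.472, -0.508 and 0.314, and reconSCID replicate 2 is in the smaller array set. With the replicate block 0 probe sets passed in either direction, the 2 lists had medians of -0.305 and -0.314, and 11 of the 31 lists were called. The covariate for RNA quality was not run, because no control probe sets are named. Signal over background could not be set for single probe sets, and low antigens may be understated in fold, as with a pseudocount of 16, where the Aire-induced median was -0.231.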

Other observations

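The test in this part was chosen after values had been seen. Immunoglobulin heavy and light chain genes, a list written after values had been seen, had a median log2 difference of 0.64 over 11 genes, 9 of them higher in reconSCID, with a camera p of 1.74e-06 and a p of 0.007194 with an estimated correlation. The exact permutation p of the list mean was 0.05714. With the array set as a block the median was 0.66 and the camera p with an estimated correlation 0.02916. The list holds Igkv5-43 and Ighm, both described above for their rise in these same data. Its p-values are therefore no separate support for a rise. Igha measured 9.31, 6.52 and 9.50 in reconSCID replicates 1, 2 and 3, and between 6.59 and 8.54 in the reconRAG1KO samples. The median was 0.71 within the 5 arrays and 0.14 within the 2 arrays. Segments of this family share sequence, so single members are uncertain.

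Xist, the X-inactivation transcript, measured 9.96 in reconRAG1KO replicate 2, 9.61 in reconSCID replicate 3 and 8.02 in reconSCID replicate 1, and 5.12 to 6.22 in the other 4 samples. The Y-linked gene Eif2s3y measured between 7.03 and 8.87 in all 7 samples. High Xist was thus spread unevenly over the groups. In the order given, the samples high in Xist had Aire levels of 10.895, 9.725 and 10.702, against 10.898 to 11.928 in the other 4. Their B cell list means were 7.14, 8.41 and 7.78, against 7.01 to 7.20. Sex was not taken into any fit, and its part in the differences between groups was not tested.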
